A study of Homo sapiens with 3 samples.

How the data were processed

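Chromatin immunoprecipitation with an antibody against mTOR was followed by sequencing of 50 bp single reads in LNCaP, an androgen-sensitive human prostate tumour cell line. Per the labels' protocols, cells were kept for 48 h in medium without steroids and then given vehicle (ethanol) or 10 nM R1881, a synthetic androgen, for 48 h. The labels give 1 sample per condition and 1 input sample. The input has no values of its own here and was not analysed here.

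Per the submitters' processing notes, the tools were BWA 0.5.9, MACS 1.4.1 and HOMER 3.18 on the human build hg19. Per the file headers, HOMER's peak annotation was run on a set of peaks called for each condition against the input, with conservation and CpG options. The threshold, the treatment of duplicate reads and any pooling of libraries are not given in the sources used here. The headers of both lists carry the same pair of identifiers, whose meaning is not given, so whether a list pools more than 1 library is open. The read depth is likewise unknown, so the precision of a count of peaks is known only through its counting interval. The peak score is the authors' own value per peak, as deposited, and its scale is not stated. Its lowest value was 1.33 in the vehicle list and 1.34 in the R1881 list, just above 1.30, which is −log10 of a 5% rate, and below 50, the usual floor of a MACS 1.4 score. Scores were used to rank or filter peaks within a list. Peak starts and ends and the distance to the nearest transcription start site (TSS), in bp, are the authors' deposited HOMER values, as are the GC and CpG fraction of each peak, given here as percentages. Coordinates are 1-based, on hg19.

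The full list of each condition was used. A deposited vehicle sheet limited to 10 kb of a TSS held 24071 peaks, all of them identical to rows of the full list, and was not used. Of 78457 vehicle peaks, 62 lay on contigs other than chromosomes 1 to 22, X and Y, as did 103 of 119948 R1881 peaks, and these were left out. In 142 vehicle rows a semicolon had cut the text of the last annotation columns. In the vehicle list 11 gene symbols on 56 peaks had been turned into dates and were restored by Entrez identifier. Symbols and gene types came from a table of GRCh38.p14 genes matched by Entrez identifier, which held 17599 of 17669 vehicle and 19081 of 19164 R1881 identifiers. None of its coordinates were used.

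Peaks of both lists were called shared at 1 bp of overlap or more. Overlap by position alone was estimated with 100 random circular shifts of the vehicle list along each chromosome. Shares carry 95% Wilson intervals and ratios of counts carry exact 95% conditional binomial intervals. These intervals cover counting error only and treat peaks as independent. A gene held a peak when HOMER assigned it a peak within 10 kb of its TSS. The 14 gene lists were fixed before the data were examined. Of the listed names 2 could not be matched, NDUFA4 among them. The share of a list's members with a peak was set against 10000 random lists of genes named in either list. The difference between conditions was set against 10000 random lists matched on deciles of the gene's summed peaks. A further measure, the ratio of all peaks assigned to a list's genes at any distance, was added after the data were seen, because most members held a peak in both lists. The same ratio divided by that of all peaks was added later still, after a first pass of the alternatives in which equal list lengths took several list ratios below 1. Both forms are given.

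Genes were named by a rule fixed before the data were examined. It takes protein-coding genes with a peak within 10 kb: the 10 with the highest-scoring R1881 peak and no vehicle peak, the 10 for the opposite case, and the 10 held by both lists with the highest lower rank of their scores. It adds up to 2 members per condition from each gene list, and a few genes that are always given, among them KLK3, KLK2, TMPRSS2, FKBP5 and MTOR. Not every gene the rule picks is named in the text. Fold enrichment was planned to break ties in score and has no column, so position did.

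The overlap code was checked against bedtools 2.31.1 on the real lists and differed by 0 vehicle peaks. In lists simulated from the 78395 vehicle peaks, a planted shared portion of 40.04% was recovered as 40.04%. A gene list planted with a raised ratio reached percentile 100. Its ratio in the randomly drawn counts was 2.94, above the planted value, so this checks the rank and not the size of a ratio. An unchanged list reached percentile 47.7. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

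Alternatives planned were other definitions of a shared peak (50% reciprocal overlap, midpoints within 200 bp, peaks within 1 kb), equal list lengths, all contigs, peaks wider than 5 kb or in the top 0.5% of scores left out, and windows of 1 kb, 50 kb or any distance. Score thresholds of 2, 10 and 20 and the leaving out of list members were added after the data were seen. Planned searches for androgen response elements and forkhead motifs need the hg19 sequence and were not run.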

Results

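The lists of mTOR-bound regions were compared between LNCaP cells given vehicle and LNCaP cells given the androgen R1881, which asks where on chromatin mTOR, a growth-regulating kinase, is found with and without androgen. After peaks on other contigs were left out, the vehicle list held 78395 peaks over 21.7 Mb and the R1881 list held 119845 peaks over 34.3 Mb. The median peak was 235 bp wide in vehicle and 245 bp in R1881. The labels gave 1 sample per condition, with 1 peak list each, so no separate replicate values could be compared and no difference between the conditions has a replicate check. Read depth is unknown, and the intervals below cover counting error only.

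Androgen-regulated loci held more mTOR peaks in the R1881 list. KLK3, which encodes prostate-specific antigen, was assigned 3 peaks with vehicle and 9 with R1881, and its neighbour KLK2 1 and 7. FKBP5, a cochaperone of steroid receptors, was assigned 4 and 16. MTOR itself was assigned 1 and 4.

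At KLK3 the highest-scoring R1881 peak lay 4034 bp upstream of the TSS at chr19:51353870-51354405 (hg19, intergenic), with a score of 67.9 in its list. A vehicle peak overlapped it at chr19:51353969-51354425, with a score of 5.53 in the vehicle list. A promoter peak at chr19:51357900-51358115 was listed with R1881 and not with vehicle. At KLK2 the single vehicle peak, at chr19:51372672-51373029, overlapped an R1881 peak, and a promoter peak at chr19:51376208-51376670 was in the R1881 list alone. At FKBP5 the highest R1881 peak, chr6:35690048-35690766 in intron 1, had a score of 174.4 and no vehicle counterpart. An intronic vehicle peak at chr6:35655619-35656655, centred 555 bp from another annotated FKBP5 TSS, had a score of 51.7 and no R1881 counterpart. At MTOR a promoter peak was in both lists, at chr1:11322772-11322991 in vehicle, and an R1881 peak in intron 4, chr1:11316227-11316765, had a score of 127.8 and no vehicle counterpart.

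TMPRSS2, an androgen-regulated serine protease gene, went the other way near its start and not farther out. Within 10 kb of the TSS it held 5 peaks with vehicle and 3 with R1881, and at any distance 11 and 22. The 4 vehicle peaks in intron 1, among them chr21:42878525-42879020, had no R1881 counterpart. The direction within 10 kb also turned with score thresholds of 10 and 20.

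**Figure D1:**
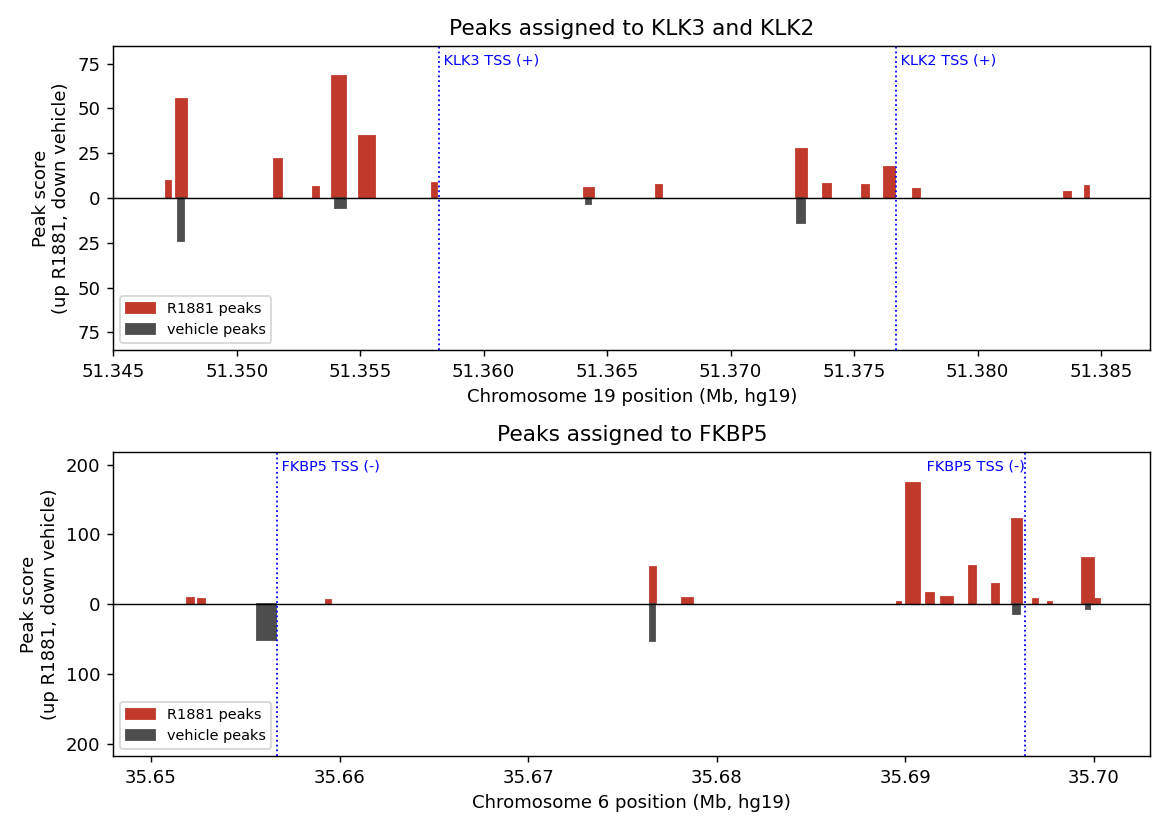
Peaks assigned to KLK3 and KLK2 (upper panel) and FKBP5 (lower panel) along hg19 in Mb, with bars spanning each peak and bar height giving the authors' score within its own list, R1881 upwards and vehicle downwards; dotted lines mark the TSS positions. KLK3 has 3 vehicle and 9 R1881 peaks, and FKBP5 4 and 16; heights are not comparable between directions.

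The vehicle peaks were largely a subset of the R1881 peaks. Of the vehicle peaks, 61271 (78.2%, 95% interval 77.9 to 78.4) were overlapped by an R1881 peak, and 17124 were not. Of the R1881 peaks, 60995 (50.9%, 50.6 to 51.2) were overlapped by a vehicle peak, and 58850 were not. Random shifts of the vehicle list gave 2.31% on average (2.12 to 2.48 over 100 shifts), 33.8-fold less. Among the top 10% of vehicle peaks by score, 99.3% were shared, against 51.6% of the lowest 10%. In the R1881 list the top 10% were shared at 79.7% (79.0 to 80.4) and the lowest 10% at 26.7%. With both lists at equal length, 62.5% of vehicle and 61.5% of R1881 peaks were shared.

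**Figure D2:**
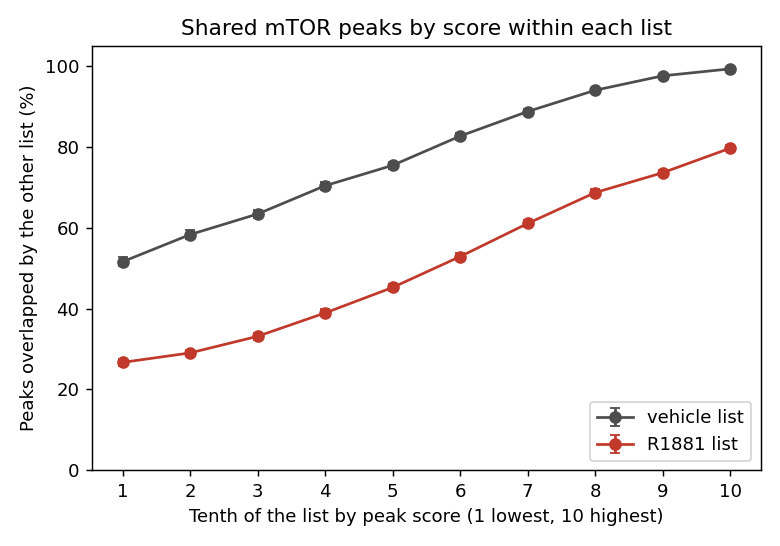
Share of peaks overlapped by the other list (y axis, %) per decile of each list by score (x axis), for vehicle and R1881, with 95% Wilson intervals. Both rise with score, from 51.6% to 99.3% in vehicle and from 26.7% to 79.7% in R1881.

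Promoters held nearly as many mTOR peaks in one full list as in the other, and introns and intergenic sequence accounted for most of the surplus. The promoter-TSS class held 9358 vehicle and 10099 R1881 peaks, a ratio of 1.08 (1.05 to 1.11), while all peaks had a ratio of 1.53 (1.52 to 1.54). The 5' UTR class had a ratio of 1.03 (0.938 to 1.13). Introns held 29497 and 49016 peaks, a ratio of 1.66 (1.64 to 1.69), and intergenic regions 35611 and 55420, a ratio of 1.56 (1.54 to 1.58). Promoters made up 11.9% of vehicle peaks and 8.43% of R1881 peaks. They made up 13.4% of shared R1881 peaks and 3.32% (3.179 to 3.468) of those in the R1881 list alone. Peaks in the vehicle list alone were also poorer in promoters, at 6.96% (6.58 to 7.35), against 13.3% of shared vehicle peaks. By distance, the ratio was 1.09 (1.06 to 1.11) within 1 kb of a TSS, 1.69 (1.65 to 1.73) from 1 to 10 kb, 1.68 (1.66 to 1.70) from 10 to 100 kb and 1.48 (1.46 to 1.51) beyond. With lists of equal length the promoter-TSS class held 9358 vehicle and 6575 R1881 peaks, and its ratio turned to 0.703 (0.681 to 0.725). Within 10 kb lay 30.7% of vehicle and 27.2% of R1881 peaks.

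**Figure D3:**
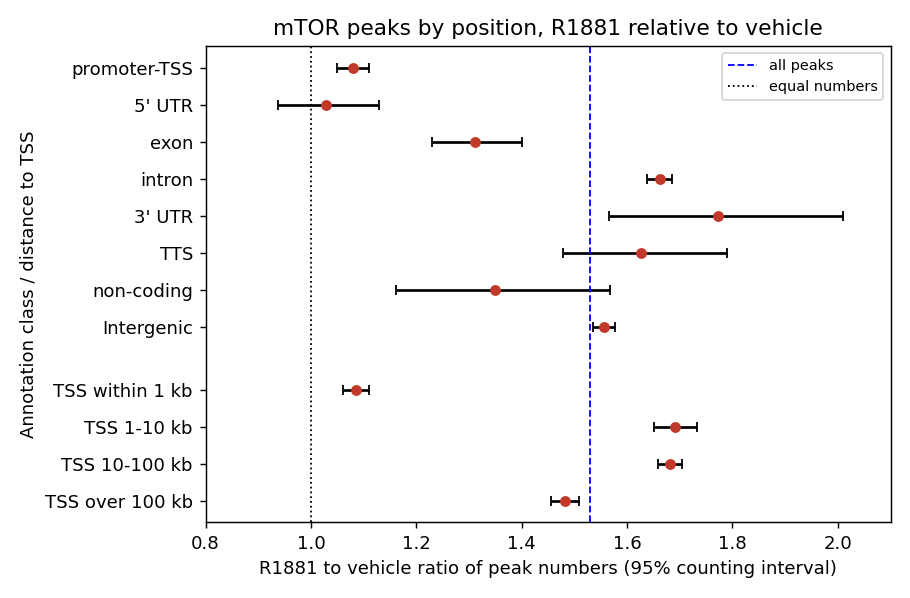
Ratio of R1881 to vehicle peak numbers (x axis) per annotation class and per distance to the TSS (y axis), with exact 95% counting intervals; the dashed line is the ratio of all peaks, 1.53, and the dotted line equal numbers. Promoter-TSS (1.08), 5' UTR (1.03) and the nearest kb (1.09) lie closest to equal numbers.

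Most genes near a peak were shared. With a peak within 10 kb of the TSS there were 13351 genes in vehicle and 15241 in R1881, of which 12545 were in both lists, 806 in vehicle alone and 2696 in R1881 alone. With lists of equal length the order turned, to 2477 genes in vehicle alone and 1472 in R1881 alone. Among the 10 highest-scoring R1881-only genes were PNLIP (pancreatic lipase), SLC26A3 (an anion exchanger), ATP6V1C2 (a proton pump subunit), LECT2, REP15, VPS26B, CNTNAP4, ADAMTS8 and PCDHGA5. None of the 10 leading peaks was overlapped by a vehicle peak. For PNLIP the peak was chr10:118312632-118313413 in an intron, with a score of 131.0, and VPS26B held 7 R1881 peaks.

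The highest-scoring vehicle-only genes were HSPE1-MOB4, PRPF31, BAG5, BORCS8, KDM5A, ZNF225, KBTBD4, URGCP, EIF1B and GPS1. All 10 of their leading peaks were overlapped by an R1881 peak that HOMER had assigned to a neighbouring gene, such as HSPD1 for HSPE1-MOB4 and NDUFS3 for KBTBD4. For 9 of these genes it was the single vehicle peak within 10 kb, so their lack of an R1881 peak within 10 kb is one of gene assignment. URGCP held 5 vehicle peaks, of which 4 were not overlapped. Over all 806 vehicle-only genes the leading peak was overlapped in 89 (11.04%), and over all 2696 R1881-only genes in 88 (3.264%).

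Genes with high-ranking peaks in both lists were POR, FAM24A, XKR7, RTBDN, INSM2, SMIM17, CELSR3, SST, DPP9 and NPAS4. The POR promoter peak, chr7:75543660-75544632 in vehicle, had the highest R1881 score of all, 209.5, and a vehicle score of 229.8.

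Members of most gene lists held a peak within 10 kb in both conditions. Of 35 androgen-responsive genes, 29 did with vehicle and 33 with R1881. By the measure planned for this comparison, the difference in members, that list lay at percentile 81.1 of matched random lists and did not stand apart. The lists at the edges were oxidative phosphorylation, with 56 and 55 members (percentile 1.10), nucleotide and one-carbon metabolism, with 30 and 29 (percentile 3.58), and genes silent in prostate epithelium, with 14 and 22 (percentile 97.455). The silent genes, markers of other cell types, had the lowest vehicle coverage, 45.2% of the 31 named (percentile 0.40 among random lists). Of the other lists, mTOR pathway genes had 33 and 36, ribosomal proteins 60 and 62, cell cycle genes 31 and 34, and glycolysis genes 21 and 23. Luminal lineage genes had 15 and 17, fatty acid and sterol genes 27 and 29, TCA cycle genes 15 and 19, lysosome genes 17 and 21, histone genes 13 and 15, and RNA polymerase III genes 9 and 9. With lists of equal length the difference turned negative for 7 lists, among them mTOR pathway and fatty acid and sterol genes, and was 0 for the silent genes, with 14 and 14. With a score of at least 10 it turned to 6 for oxidative phosphorylation and 8 for nucleotide and one-carbon metabolism, and was 1 for the silent genes. For the androgen-responsive genes the difference was then 8, and it was larger with a score of at least 20. No percentile was computed at these thresholds.

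Counted at any distance, a measure added after the data were seen, the androgen-responsive genes had 242 vehicle and 593 R1881 peaks. Their ratio of 2.45 (2.11 to 2.86) lay above the middle 95% of matched random lists (1.301 to 1.748). Of the 35 genes 32 had more R1881 peaks, among them MAF (26 with vehicle and 78 with R1881), ABCC4 (16 and 46), ELL2 (3 and 19) and CENPN (5 and 27), while ACP3 (28 and 27) and MED28 (3 and 2) had fewer. Relative to all peaks the ratio was 1.60 (1.38 to 1.87), the highest of the 14 lists under each of the 7 settings for which it was computed. Fatty acid and sterol genes had a ratio of 2.00 (1.60 to 2.51, percentile 99.8), with ELOVL6 at 2 and 18 and SCAP at 2 and 15. TCA cycle genes had 1.94 (1.49 to 2.54, percentile 97.545), with OGDH at 7 and 15 and PC at 3 and 11. With lists of equal length the ratio was 1.60 (1.36 to 1.89) for androgen-responsive genes and 1.28 (1.004 to 1.643) for fatty acid and sterol genes. For TCA cycle genes it was 1.32 (0.991 to 1.76), which includes 1. Relative to all peaks the TCA ratio was 1.27 in the full lists, 1.37 with a score of at least 10 and 0.848 with a score of at least 20.

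The other lists had ratios from 1.29 to 1.82, against 1.53 for all peaks, each within the middle 95% of its matched random lists. Oxidative phosphorylation (1.299), ribosomal protein (1.331) and cell cycle genes (1.29) lay at percentiles 2.71, 6.17 and 6.24. Luminal lineage genes had 1.56 (1.295 to 1.886), with FOXA1 at 50 and 56 and GATA2 at 10 and 6. Genes of the mTOR pathway had 1.497, with TFEB, a regulator of lysosomal genes, and TSC1, an mTOR inhibitor, holding promoter peaks in both lists. Nucleotide genes had 1.48, glycolysis 1.67, lysosome 1.69, histone 1.56, RNA polymerase III 1.65 and silent genes 1.82 (percentile 92.8). With lists of equal length 8 of these list ratios were below 1.

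Many of the highest-scoring members of the gene lists had their highest peak within 10 kb of the TSS in the same class in both lists. RPS14 and RPL6, ribosomal protein genes, MCM7 and BUB1B of the cell cycle list, NDUFS7 of respiratory complex I, PKM, ENO1 and PFKFB3 of glycolysis, CYP51A1 of sterol synthesis, ATF4, GABARAP and LAMP1 each had it at a promoter. The highest-scoring peaks of GABARAPL1 lay in an exon, and those of VTRNA1-3, a vault RNA gene, at the transcript's end. VTRNA1-1 and RPPH1 held promoter peaks, and H4C8, H1-2, COX6A1, ACACB and SLC17A7 intergenic ones. SYN1, a neuronal gene of the silent list, also held a promoter peak in both lists. For other members the class of the highest-scoring peak within 10 kb differed between the lists. It was a promoter in vehicle and an intron in R1881 for SC5D, a promoter and intergenic for CAMKK2 and GRHL2, and an intron and intergenic for ELL2. STEAP1, NDUFA11, TKT and ATIC differed in class as well, but their peaks in both lists overlapped close to the TSS, so only the annotated class differed. SPDEF was intergenic in both.

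**Figure D4:**
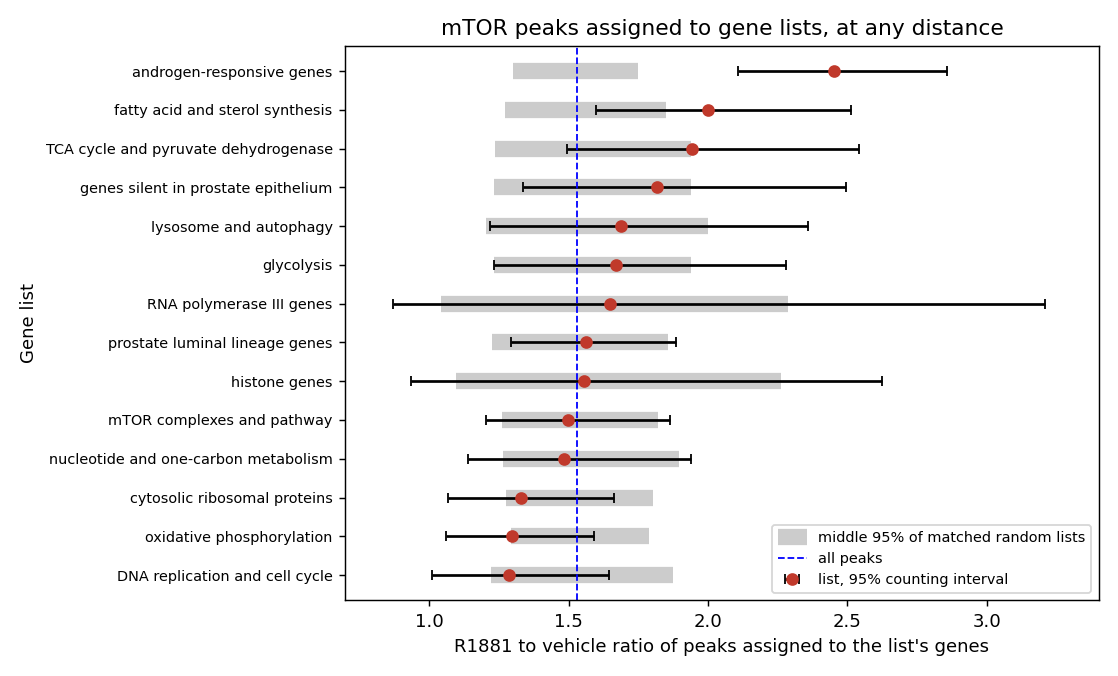
Ratio of R1881 to vehicle peaks assigned to each gene list (x axis; y axis, lists), as points with exact 95% counting intervals; grey bars are the middle 95% of matched random lists and the dashed line is the ratio of all peaks, 1.53. The androgen-responsive list, at 2.45, is the list whose interval lies above its grey bar.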

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

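Peaks on unplaced and alternative contigs were left out of the report's comparisons, though kept in 1 alternative, and numbered 62 in vehicle and 103 in R1881. They are given because they exceed the 3 counts that a count of 0 allows, a low limit that says no more about them. None was mitochondrial. The tests of explanations in this part were chosen after the results were seen, while equal list lengths and the count of members with a peak within 10 kb were planned.

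The R1881 surplus lay mostly away from promoters. Equal list lengths take off the low-scoring peaks that a longer list may add. Promoters then made up 8.39% (8.20 to 8.58) of R1881 peaks, against 11.9% of vehicle peaks. By score, promoters made up 10.1% of the lowest 10% of R1881 peaks and 8.57% of the highest 10%. Taking off low scores could thus hardly raise their share. The values argue against low-scoring peaks as the whole cause. A longer list that adds peaks at all scores stays open. A deeper or better enriched R1881 library stays open, since depth and enrichment are unknown. Of the top 10% of R1881 peaks by score 79.7% were shared, against 99.3% the other way. How large a share a more sensitive library would leave unshared is not known, so these values do not decide. The androgen treatment may be a cause, but with 1 list per condition it cannot be told apart from this or from other differences between cultures or immunoprecipitations.

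Androgen-responsive genes had a ratio of 2.45 R1881 to vehicle peaks. Large gene territories are argued against by matched random lists, whose middle 95% ended at 1.75, below the list's lower bound of 2.11. The longer R1881 list is argued against as the whole cause by equal list lengths, which left a ratio of 1.60 (1.36 to 1.89). Without MAF and ABCC4 the ratio was 2.345. The planned measure, members with a peak within 10 kb, did not set the list apart (percentile 81.1), and the treatment may be the cause but cannot be told apart from other differences of 1 list per condition.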

How the results depend on the processing

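The score thresholds of 2, 10 and 20, the ratio relative to all peaks and the leaving out of list members were chosen after seeing the data. Planned thresholds of 100 on the MACS −10log10 p and 10 on fold enrichment were not run, since no column holds them, nor were the motif searches. Scores are assumed to mean the same in both lists when a threshold is used. For the main results 546 alternative values stayed close to the reported value, 147 moved and 39 changed sides, and for single genes and covered length 322 stayed, 16 moved and 7 changed sides. All contigs kept moved no result, and leaving out MAF, ABCC4 or shared members moved neither list ratio beyond its interval. Unknown read depth limits every count.

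Other definitions of sharing moved the shares of vehicle and R1881 peaks shared to 69.0% and 45.1% (reciprocal 50%; 100.1-fold over shifts), 75.9% and 49.6% (midpoints; 45.7-fold) and 82.7% and 56.8% (within 1 kb). Leaving out extreme peaks gave 77.7% and 50.6%, and 1 more RNA polymerase III member with R1881 than with vehicle.

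Equal lengths, by construction, gave 78395 R1881 peaks and a ratio of 1. Sharing was then 62.5% and 61.5% (37.8-fold), with 26.1% of R1881 peaks within 10 kb, 0.702% in 5' UTRs, 39.6% in introns and 47.8% intergenic. Genes held by vehicle alone numbered 2477 and by R1881 alone 1472. List ratios were 1.60 (androgen), 1.35 (RNA polymerase III), 1.1 (glycolysis), 1.32 (TCA), 1.28 (fatty acid) and 1.13 (lysosome). The RNA polymerase III list had only 17 vehicle and 28 R1881 peaks in the full lists. Ratios were below 1 at 0.984 (luminal), 0.925 (oxidative phosphorylation), 0.804 (nucleotide), 0.979 (mTOR), 0.8897 (ribosomal), 0.910 (cell cycle), 0.889 (histone) and 0.970 (silent). Relative to all peaks, luminal, histone and silent genes thereby turned from above to below 1, at the same 0.984, 0.889 and 0.970. The member difference, R1881 minus vehicle, turned to -1 (TCA), -2 (fatty acid), -4 (mTOR), -2 (lysosome), -3 (ribosomal), -4 (cell cycle) and -3 (histone), and moved to -8 (nucleotide) and 0 (silent, with 14 R1881 members). A shorter R1881 list has fewer peaks to assign.

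A window of 1 kb held 17.1% of vehicle and 12.1% of R1881 peaks, 1432 genes in R1881 alone, 2 and 5 silent genes, and a ribosomal difference of -1. A window of 50 kb held 59.6% and 59.4%, 23 silent genes with vehicle, differences of -2 (TCA) and 1 (oxidative phosphorylation), and more R1881 than vehicle peaks at SST (2 more) and TMPRSS2 (6 more). At any distance 463 genes were in vehicle alone and 26 silent genes were held with vehicle, the differences were -2 (TCA) and 1 (oxidative phosphorylation), SST had 2 and TMPRSS2 11 more R1881 peaks. The cause at SST was not tested.

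A score of at least 2 gave 50.5% of R1881 peaks shared and a ratio of 1.54. A score of at least 10 left 28690 vehicle and 47320 R1881 peaks, a ratio of 1.65, with 78.9% and 47.7% shared (62.8-fold), 31.0% and 26.1% within 10 kb, 13.6% and 8.64% at promoters, 33.7% and 38.8% in introns, 48.0% and 48.4% intergenic, 0.373% and 0.537% in 3' UTRs, 0.798% and 0.864% at TTS, and 0.687% of R1881 peaks in 5' UTRs. Genes in both lists numbered 6128. Members with vehicle and R1881 were 11 and 13 (glycolysis), 8 and 10 (TCA), 10 and 18 (nucleotide), 18 and 23 (mTOR), 7 and 9 (lysosome), 30 and 41 (ribosomal), 15 and 18 (cell cycle) and 7 and 8 (silent), with vehicle 18 (androgen), 32 (oxidative phosphorylation) and 13 (fatty acid), and with R1881 9 (histone). Differences moved to 8 (androgen), 9 (fatty acid), 11 (ribosomal) and 1 (silent), and turned to 6 (oxidative phosphorylation) and 8 (nucleotide). Ratios were 3.07 (androgen), 1.64 (oxidative phosphorylation) and 1.19 (silent). Relative to all peaks, sides changed for nucleotide (1.14), lysosome (0.857), histone (0.720), RNA polymerase III (0.937) and silent genes (0.719). TMPRSS2 had 1 more R1881 peak.

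A score of at least 20 left 12420 and 21630 peaks, a ratio of 1.74, with 79.8% and 45.8% shared (118.0-fold), 31.2% and 25.6% within 10 kb, 14.3% and 8.78% at promoters, 31.0% and 36.9% in introns, 49.8% and 50.1% intergenic, 0.733% and 0.846% at TTS, 0.467% and 0.388% non-coding, 2.23% of vehicle peaks in exons and 0.322% in 3' UTRs, and 0.583% of R1881 peaks in 5' UTRs. Genes in both lists numbered 2890. Members were 7 and 18 (androgen), 4 and 3 (luminal), 4 and 5 (glycolysis), 5 and 6 (TCA), 15 and 14 (oxidative phosphorylation), 11 and 14 (fatty acid), 6 and 6 (nucleotide), 10 and 15 (mTOR), 4 and 7 (lysosome), 16 and 16 (ribosomal), 6 and 8 (cell cycle), 6 and 3 (histone) and 3 and 4 (silent). Differences moved to 11 (androgen), 1 (RNA polymerase III) and 1 (silent), and turned to -1 (luminal) and -3 (histone). Ratios were 4.43 (androgen), 2.11 (luminal), 1.48 (TCA), 3.23 (fatty acid), 2.29 (nucleotide) and 0.9 (histone, from above to below 1). Relative to all peaks, values were 2.54 (androgen) and 1.86 (fatty acid), and sides changed for TCA (0.848), nucleotide (1.31), lysosome (0.709), histone (0.517), RNA polymerase III (0.820) and silent genes (0.790). DPP9 had 2 more and TMPRSS2 1 more R1881 peak. Higher thresholds leave fewer peaks; the cause of the other shifts was not tested.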

Other observations

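Repeats differed between shared and list-specific peaks, and all values and tests in this part were chosen after the data were seen. Peaks in LTR elements made up 17.1% of shared vehicle peaks, 9.34% of vehicle-only peaks and 11.8% of R1881-only peaks, and their share was higher among high scores, from 8.14% in the lowest to 30.6% in the highest vehicle decile. Peaks in SINE elements made up 6.61% of shared vehicle peaks, 10.8% (10.4 to 11.3) of vehicle-only peaks and 14.1% (13.8 to 14.4) of R1881-only peaks. Of 191 repeat subfamilies with at least 100 peaks, the DNA transposons Tigger3b (26 vehicle and 201 R1881 peaks) and Tigger3a (25 and 189) had the highest ratios, followed by the LTR element MSTA (35 and 166). The related Tigger1 had 378 and 445. MER52A (379 and 313) and LTR1D (103 and 73) had fewer R1881 peaks.

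Over all genes, with peaks counted at any distance, MAF (26 vehicle and 78 R1881), MIR620 (36 and 84) and TBL1XR1 (48 and 95) had the most additional R1881 peaks. PARD3 (25 and 66), PLA2G4A (31 and 70), KCNN2 (33 and 72) and KCNMA1 (40 and 78) followed. The genes with the most additional vehicle peaks were MBL2 (84 vehicle and 51 R1881), BCHE (69 and 42) and GHITM (75 and 56). Most of these peaks lay beyond 10 kb of the TSS. Within 10 kb MAF held 4 vehicle and 6 R1881 peaks, TBL1XR1 3 and 9 and PARD3 3 and 2. MIR620 and MBL2 each held 0 and 0. Of 2571 bins of 1 Mb with at least 20 peaks, 100 had fewer R1881 than vehicle peaks. Over all bins, the distance from the ratio of all peaks had an SD of 1.01 in units of a counting error that treats the lists as independent. Most vehicle peaks are shared with the R1881 list, so this unit is too large. The SD therefore does not show whether bins vary beyond counting error. The farthest bins in each direction were chromosome 3 from 166 to 167 Mb (73 vehicle and 44 R1881, at -4.61) and chromosome 13 from 110 to 111 Mb (9 and 50, at 4.30).

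Pooled, Tigger3a and Tigger3b had a ratio of 7.65 (5.70 to 10.5), and 345 of the 390 R1881 peaks had no vehicle counterpart. Over the young families AluY, L1PA5 and L1PA6 the highest ratio was 2.56 and the highest upper bound 3.19. L1PA4 had a ratio of 2.25 and L1PA3 one of 1.78. All lay below the pooled ratio, but above the 1.53 of all peaks. How far short reads from near-identical copies would raise a family is not known, so this explanation stays open. An amplified or clustered region is argued against by the chromosome with the most of these peaks, which held 10.3% of them. Adjusted for 191 subfamilies, and for counting error only, the lower bounds of the ratio were 3.78 for Tigger3b and 3.64 for Tigger3a. The treatment may be a cause, for example through a sequence motif in these elements, but no sequence was searched and with 1 list per condition it cannot be told apart from other differences.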
